A study of Mus musculus with 26 samples.

How the data were processed

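CD4 Treg and Tconv cells were purified from the CNS or the dLN of tamoxifen-treated mice at day 14 of EAE, and their polyadenylated RNA was extracted with a NucleoSpin RNA XS kit. Libraries were made with SMART-Seq v4, which copies full-length transcripts without strand information, followed by Nextera. According to the submitters' processing notes, reads were checked with FastQC, trimmed with Trimmomatic, aligned to mm10 with STAR 2.5.3a and quantified per gene with RSEM 1.2.28. Each of the 26 deposited tables held expected counts, the read numbers that RSEM assigned to each gene, for 24848 gene symbols. The deposited TPM and FPKM columns were computed by the authors' RSEM run from the same counts, scaled to gene length and library total. The TPM and FPKM columns were checked against the counts and not used here. The tables did not list the 13 mitochondrially encoded genes.

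The expected counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3, with jsonlite 2.0.0 and data.table (version 1.17.8) as readers. Genes with low counts were removed with filterByExpr, which left 13054 genes with 26 libraries and 13500 with 25, and libraries were scaled with TMM factors. A single quasi-likelihood model with 8 group means was fitted, so that all groups share the estimate of spread, and each comparison was a contrast of these means. The 11 contrasts were icKO against Ctrl in each of 4 populations, CNS against dLN in control Treg and Tconv cells, Treg against Tconv in each tissue of control mice, and 3 interaction contrasts. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05. SE is the log2 fold change divided by the square root of its F statistic. These p-values use the spread pooled over all 8 groups, not that of the compared groups alone, and the groups differed in spread. Quality weights from limma, higher for libraries with less spread, were 0.408 to 0.884 in CNS Treg and 0.882 to 3.27 in dLN Treg libraries. Replicates of a group are read as separate mice.

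Gene lists were tested with camera, which compares a list with all other genes, at its preset correlation of 0.01 and again with an estimated correlation, and with fry, which asks whether a list moves on balance in 1 direction. Of 35 lists, 33 had at least 3 tested members, and adjustment ran over the lists of a comparison. Lists of transcripts of other cell types were included. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 drew the plots. Gene positions came from the GENCODE annotation of GRCm38, the assembly also called mm10.

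Sample groups, lists, contrasts, tests and the rule for named genes were fixed before the data were examined. The rule names Tnfrsf1b and Foxp3 in each comparison, and the 10 largest rises and 10 largest falls in genotype comparisons and their interactions. In the other comparisons it names 5 and 5. These genes had to be called, to reach a mean of 10 CPM in 1 group and, outside interactions, to have no overlap between the groups' libraries. It adds up to 3 called members per list with the smallest p, and the 5 genes with the smallest p where fewer than 5 were called. Genes without an official symbol and receptor variable segments were left out of the largest changes. Some genes that the rule names are not reported here. The fit of 25 libraries was added after seeing the data, and the rule was applied to it in the same way.

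Alternatives were DESeq2 size factors inside edgeR, the DESeq2 1.42.0 Wald test, limma 3.58.1 voom with quality weights, no filter, a filter of 10 CPM in 3 libraries, models of the compared groups alone, a replicate block and leaving out each library in turn. A further alternative left out the 5 CNS Tconv libraries whose file names disagreed with their labels. Folds against a group at 0 were computed against a floor of 3 counts per library, and such floors cover counting error only. With total counts of 7.78 to 18.5 M per library, 3 counts equal 0.205 CPM in CNS Tconv Ctrl libraries of the fit of 25.

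The procedure was tested on simulated data with the group sizes of these libraries and 1 dispersion per gene, shared by all groups. With 26 libraries, 2-fold changes at 10 CPM or more were recovered for 13.2% of genes in CNS Treg, 12.2% in dLN Treg, 15.5% in CNS Tconv and 21.4% in dLN Tconv cells, and 4-fold changes for 43.6%, 39.2%, 50.0% and 40.5%. With 25 libraries these shares were 46.8%, 50.0%, 55.0% and 38.7% for 2-fold and 82.4%, 88.7%, 94.4% and 79.7% for 4-fold changes. camera found 8 of 8 simulated lists raised 1.5-fold and 0 of 8 unchanged lists. Simulated genes varied independently of each other, so this step could not show false list calls that come from correlated genes. Nor could it show how unequal spread between the groups changes the recovered shares. The library left out of the fit of 25 was simulated with the same dispersions as the others.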

Results

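Bulk RNA sequencing measured the transcripts of 26 samples of CD4 T cells from C57BL/6 mice at day 14 of experimental autoimmune encephalomyelitis (EAE), a mouse model of multiple sclerosis. The samples were Foxp3-positive regulatory T cells (Treg) or conventional T cells (Tconv), from the central nervous system (CNS) or the draining lymph nodes (dLN). Control mice (Ctrl) carried a tamoxifen-inducible Cre in the Foxp3 locus. The conditional knockout mice (icKO) also carried floxed alleles of Tnfrsf1b, the gene of the TNF receptor TNFR2, and tamoxifen was given from day 7 to day 14. Each of the 8 groups of cell type, tissue and genotype held 3 samples, except CNS Tconv Ctrl and CNS Tconv icKO with 4 each. The deposited tables listed 24848 genes per library. Values below are TMM-normalised counts-per-million values (CPM), given as mean ± SD over these replicates, and log2 fold changes ± SE with adjusted p from edgeR.

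The total expected count was 12.4 to 18.5 M in 25 libraries, with a median of 14.4 M and 11089 to 14259 genes above 0. The library labelled dLN Tconv icKO replicate 3 held 7.78 M counts over 6005 genes. Its highest rank correlation with any other library was 0.665, against at least 0.957 for each of the other 25. A fit of all 26 libraries was planned. A fit of 25 libraries, without that library, was added after seeing the data. The common dispersion, a measure of the spread between replicates shared by all groups, was 0.364 in the fit of 26 and 0.142 in the fit of 25. Both results are given for each comparison, and values without a mention come from the fit of 26. All genes called in the fit of 26 were also called in the fit of 25, in the same direction.

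**Figure D1:**
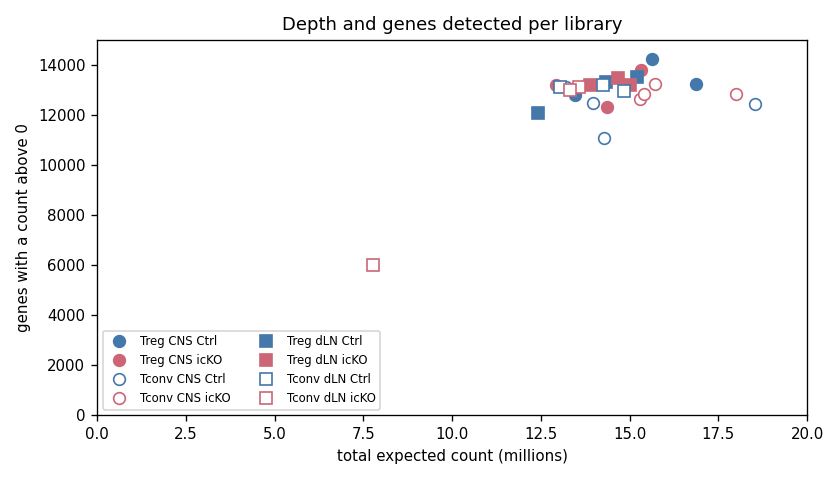
Total expected count (M, x axis) and number of genes with a count above 0 (y axis), 1 point per library. Circles are CNS, squares dLN, filled symbols Treg, open symbols Tconv, blue Ctrl and red icKO. The dLN Tconv icKO library at 7.78 M counts and 6005 genes lies apart from the other 25.

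Tnfrsf1b, located on chromosome 4 from 145213463 to 145246870 (GRCm38, minus strand), had a higher mean in Treg than in Tconv libraries of control mice in both tissues; the difference passed in the dLN alone in the fit of 26 and in both tissues in the fit of 25. It did not pass the test for a lower level in icKO Treg libraries. In CNS Treg libraries it averaged 407 ± 89.4 CPM in icKO and 615 ± 135 CPM in Ctrl (n = 3 each), a log2 fold change of -0.59 ± 0.60 (adjusted p = 1, and 0.56 in the fit of 25). Adjusted over the list alone, it was the 1 member of the TNF receptor list that passed there in the fit of 25. In dLN Treg libraries the means were 637 ± 6.76 and 806 ± 53.9 CPM, a log2 fold change of -0.34 ± 0.59 (adjusted p = 1 in either fit). The 3 dLN Treg icKO libraries all lay below the 3 Ctrl libraries, while the CNS Treg groups overlapped. Both SE values come from the fit of 26, where all groups share the estimate of spread. That fit includes the library labelled dLN Tconv icKO replicate 3. It held 3.22 CPM of Tnfrsf1b by library total, against 130 ± 8.22 CPM in the other dLN Tconv libraries (n = 5). The SE values therefore do not measure the spread among the Treg libraries alone. In CNS Tconv libraries the gene averaged 340.2 ± 50.8 CPM in icKO and 208 ± 26.3 CPM in Ctrl (n = 4 each), a log2 fold change of 0.71 ± 0.52 (adjusted p = 1); it rose in the fit of 25 (adjusted p = 0.0091). In dLN Tconv libraries the log2 fold change was -0.50 ± 0.60 with all 26 libraries and 0.07 ± 0.18 with 25 (adjusted p = 0.84 and 1). The counts cover the whole gene, and the labels do not state which exons the floxed allele removes. CNS Treg libraries also held transcripts of myeloid cells, described below, and which cells gave their Tnfrsf1b counts was not tested.

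Foxp3, the lineage transcription factor of Treg cells on chromosome X, averaged 36.5 ± 21.6 CPM in CNS Treg Ctrl and 50.3 ± 18.6 CPM in CNS Treg icKO libraries. In dLN Treg libraries it averaged 48.7 ± 9.0 CPM in Ctrl and 43.8 ± 6.28 CPM in icKO. Tconv libraries held 0.879 ± 0.487 CPM in CNS Ctrl and 1.02 ± 0.12 CPM in dLN Ctrl. Foxp3 passed the test in none of the 4 genotype comparisons in either fit, with adjusted p of 0.079 or more.

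**Figure D2:**
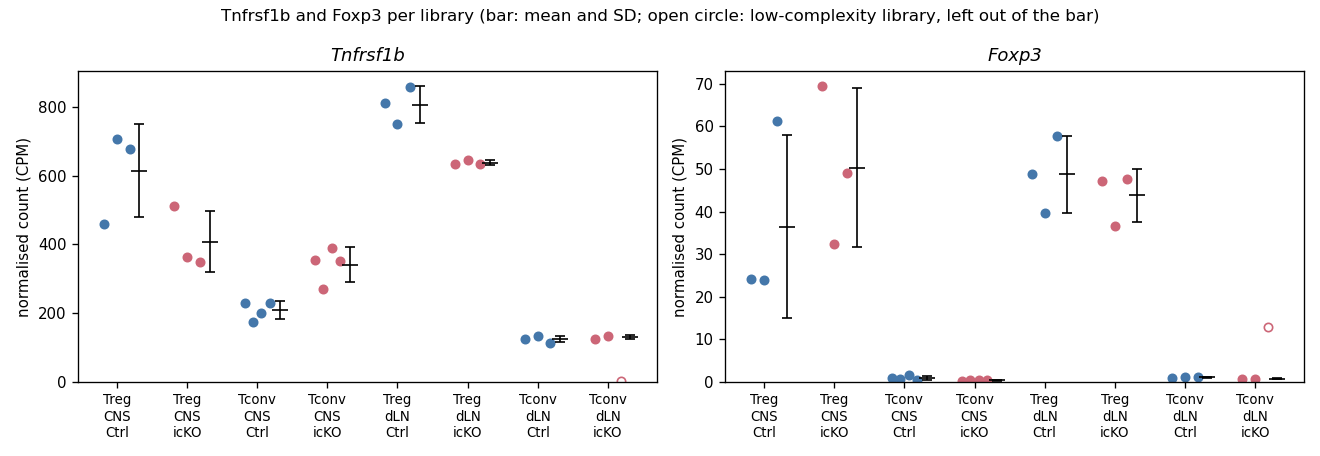
Normalised count (CPM, y axis) of Tnfrsf1b and Foxp3 in each library by group (x axis), blue for Ctrl and red for icKO. Bars give mean and SD without the open circle, the dLN Tconv icKO library of 6005 genes. Foxp3 is high in the Treg groups, and the 3 dLN Treg icKO libraries lie below the 3 dLN Treg Ctrl libraries for Tnfrsf1b.

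The first genotype comparison asked whether Treg cells of the inflamed CNS differ between icKO and Ctrl mice. No single gene passed the test, and 4 gene lists passed camera with its preset correlation. With 25 libraries, cell cycle genes lay lower in icKO CNS Treg libraries (median log2 fold change -0.43 over 40 genes, camera adjusted p = 5.3e-06, adjusted p = 0.99 with an estimated correlation). In the same fit, genes of oxidative phosphorylation, the respiratory chain of mitochondria, lay higher (median 0.14 over 44, camera adjusted p = 5.2e-06, adjusted p = 0.99 with an estimated correlation), as did genes of cholesterol synthesis (median 0.30 over 20, camera adjusted p = 2.6e-05, adjusted p = 0.25 with an estimated correlation). Markers of CD8 T and NK cells lay higher too in the fit of 25, with a median of 1.29 over 10 genes (camera adjusted p = 1.0e-05, adjusted p = 0.14 with an estimated correlation). With all 26 libraries the same 4 lists passed at the preset correlation, and the CD8 T and NK list with an estimated correlation (adjusted p = 0.035). In the fits of 25 less 1 library, the cell cycle call was lost without CNS Treg Ctrl replicate 3 (adjusted p = 0.77), the library with the highest summed CPM of library total for these genes (5282, against 2370 to 3573 in the other 5). Cholesterol synthesis was called in 4 of these 6 fits (adjusted p = 0.063 without Ctrl replicate 3), oxidative phosphorylation in 5 (0.097 without icKO replicate 3) and the CD8 T and NK list in all 6.

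edgeR called 0 of 13054 genes in the fit of 26 and 0 of 13500 in the fit of 25, with 256 and 915 genes at an unadjusted p under 0.05. The 256 fall short of the share of 0.05 that no effect would give, so the shared spread of the fit of 26 may be too wide here. DESeq2 called 2 genes and limma 0. Among the 5 genes with the smallest p in the fit of 25, Cd8b1, a chain of the CD8 coreceptor, had a log2 fold change of 1.70 ± 0.33 (adjusted p = 0.22) and Prmt5, an arginine methyltransferase, -0.72 ± 0.14 (adjusted p = 0.22). The other 3 of that fit, Fam53c, Pemt and Gm20604, had values of -0.68, 4.18 and 1.22 with adjusted p of 0.24 to 0.27. No list member passed over all genes. Adjusted over the list alone, 1 member of the CD8 T and NK list was higher and 1 of the TNF receptor genes, Tnfrsf1b, lower in the fit of 25. Without CNS Treg icKO replicate 1 the fit of 25 called 13 genes, 12 of them lower.

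In dLN Treg cells, the same comparison in the lymph nodes that drain the site of immunisation, no single gene passed the test. Genes of oxidative phosphorylation lay slightly higher in icKO libraries in both fits (median log2 fold change 0.09 over 44 genes, camera adjusted p = 0.0014, adjusted p = 0.9 with an estimated correlation; 0.07 and 0.017 in the fit of 25, adjusted p = 0.92 with an estimated correlation). Genes of cholesterol synthesis lay higher in the fit of 25 (median 0.16, camera adjusted p = 0.024, adjusted p = 0.83 with an estimated correlation) and did not pass in the fit of 26 (adjusted p = 0.11). Glycolysis genes passed in the fit of 26 (median 0.11, camera adjusted p = 0.047, adjusted p = 0.9 with an estimated correlation) and not in the fit of 25 (adjusted p = 0.12). Markers of other cells moved with them: the B cell list (median 0.54 with members at 0 in a group set to their bound, camera adjusted p = 0.0016, adjusted p = 0.22 with an estimated correlation), the astrocyte list (0.88, camera adjusted p = 0.0046, adjusted p = 0.28 with an estimated correlation) and the list of endothelium and fibroblasts (0.12, camera adjusted p = 0.0012, adjusted p = 0.22 with an estimated correlation) lay higher in icKO. The camera tests do not use these bounds. Of 11 tested endothelium and fibroblast markers 6 were at 0 in at least 1 group, and their median without bounds was 1.92. In the fits of 25 less 1 library, oxidative phosphorylation was called in all 6, cholesterol synthesis in 3 (adjusted p = 0.31 without icKO replicate 1), the B cell list in 2, the list of endothelium and fibroblasts in 1 and the astrocyte list in 0.

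edgeR called 0 genes in both fits, with 56 genes at an unadjusted p under 0.05 in the fit of 26 and 146 in the fit of 25. Of the 13054 and 13500 genes tested, these are far under the share of 0.05 that no effect would give. The shared spread may therefore be too wide for dLN Treg libraries, and the lack of calls is weak evidence of no change. With quality weights limma had 668 genes at an unadjusted p under 0.05. DESeq2 called 5 genes and limma 2. Slpi, a secreted inhibitor of leukocyte proteases, had a log2 fold change of 2.38 ± 0.54 and Ide, the insulin-degrading enzyme, -0.79 ± 0.22 in the fit of 25 (adjusted p = 1 each). Ide averaged 179 ± 24.2 CPM in icKO and 309 ± 29.2 CPM in Ctrl, as scaled for that fit (n = 3 each). The other genes among the 5 with the smallest p stayed under 5 CPM in both groups. No member of any list passed, over all genes or adjusted over the list alone. Without dLN Treg icKO replicate 1 the fit of 25 called 1 gene.

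The Cre acts in Foxp3-expressing cells, so the comparison of CNS Tconv cells asked how T cells of the inflamed CNS differ when the floxed alleles are targeted in other cells, the Treg cells. They had more called genes between the genotypes than the other 3 populations with edgeR, DESeq2 and limma. As a list, genes of naive and central T cells were lower in icKO libraries, also with an estimated correlation in both fits. Lists of glycolysis and inflammatory cytokine genes were higher, with an estimated correlation in the fit of 26 (adjusted p = 0.02 and 0.037) and not in the fit of 25 (0.22 each). Ccr7, the chemokine receptor that guides T cells into lymph nodes, fell from 719.8 ± 76.9 to 181 ± 98.5 CPM (log2 fold change -1.99 ± 0.26, adjusted p = 0.00077, n = 4 each). Hif1a, a transcription factor that drives glycolytic genes, rose from 503 ± 175 to 1439 ± 321 CPM (1.52 ± 0.29, adjusted p = 0.046).

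The fit of 26 called 12 genes, 5 higher and 7 lower. Besides Hif1a, the genes that rose were Mapkapk3, a kinase of the p38 pathway (0.99 ± 0.18), Rab8b, a GTPase of vesicle transport (0.84 ± 0.16), Tpm4, a tropomyosin (0.73 ± 0.14), and Lcp1, the actin-bundling protein L-plastin (0.52 ± 0.10). Besides Ccr7, the genes that fell included Ly6c1 (-2.38 ± 0.32), H2-Ob (-2.13 ± 0.40), the IL-6 receptor gene Il6ra (-1.62 ± 0.29), Ndrg3 (-1.06 ± 0.14) and Rpl35 (-0.69 ± 0.13), with adjusted p from 0.00098 to 0.046 for these 9 genes. DESeq2 called 120 genes and limma 445.

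The fit of 25 called 419 genes, 213 higher and 206 lower. Its largest rises included Serpine2, a protease inhibitor (2.84 ± 0.74, adjusted p = 0.04), Hk2, hexokinase (2.20 ± 0.36, 0.0029), Slc16a3, the lactate exporter MCT4 (2.01 ± 0.37, 0.0061), Tnfrsf9, the costimulatory receptor 4-1BB (1.97 ± 0.49, 0.031), and Asns, asparagine synthetase (1.91 ± 0.35, 0.0061). In this fit, Itga3, Ctla2b, Il1r2, Cdkn1a and Tnfsf9 rose by 1.85 to 2.02 on the log2 scale. Its largest falls were Dapl1 (-2.71), Tmie (-2.60) and Ppic (-2.55), followed by Ly6c1, Igfbp4, H2-Ob, Atp1b1, Cnn3, Ephx1 and Ccr7 at -2.38 to -1.99. Dapl1 and Igfbp4 belong, with Ccr7, to the list of naive and central T cells.

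Of 18 genes of naive and central T cells, 2 fell in the fit of 26 and 12 in the fit of 25; adjusted over the list alone the counts were 9 and 14. Their median log2 fold change was -0.86, and the list was lower than other genes in both fits, also with an estimated correlation (adjusted p = 0.0048 and 0.0022). Foxp1, a transcription factor of naive T cell quiescence, fell by 1.04 on the log2 scale in the fit of 25. Of 21 glycolysis genes, 1 rose in the fit of 26 and 9 in the fit of 25, and 14 and 18 adjusted over the list alone. The list had a median of 0.54 and camera adjusted p = 4.7e-18 (adjusted p = 0.02 with an estimated correlation, and 0.22 in the fit of 25). Slc2a3, a glucose transporter, rose by 1.05 ± 0.19 in the fit of 25.

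Besides glycolysis, 4 lists were higher in icKO CNS Tconv libraries with all 26 libraries and an estimated correlation. Inflammatory cytokines had a median log2 fold change of 2.39 over 19 genes, or 2.25 with members at 0 in a group set to their bound (camera adjusted p = 5.9e-09, adjusted p = 0.037 with an estimated correlation); 2 rose and 1 fell in the fit of 25, and 11 and 2 adjusted over the list alone. In the fit of 25, Lta, lymphotoxin alpha, rose by 1.70 ± 0.46 (adjusted p = 0.046), and Il1a, at 0 in all 4 Ctrl libraries, was at least 5.86-fold higher (0.037); neither passed in the fit of 26 (0.34 and 0.22). Th1 genes had a median of 0.48 (camera adjusted p = 4.4e-08, adjusted p = 0.037 with an estimated correlation), and 3 of 17 rose in the fit of 25, among them Il18rap and Il18r1 at 1.41 and 0.80. Tissue residency genes (median 0.70, camera adjusted p = 2.4e-08, adjusted p = 0.037 with an estimated correlation) and effector Treg genes (median 0.54, camera adjusted p = 0.00028, adjusted p = 0.037 with an estimated correlation) were higher as well. In the fit of 25 these 4 lists had an adjusted p of 0.22 with an estimated correlation. Treg core genes moved with them in the fit of 25 (median 0.40, 4 of 24 rose and 2 fell, camera adjusted p = 0.016, adjusted p = 0.24 with an estimated correlation; camera adjusted p = 0.06 in the fit of 26), and the list was called in 6 of the 8 fits of 25 less 1 library (0.063 without icKO replicate 1). Its summed CPM of library total was 3468 to 4260 in icKO and 2359 to 2967 in Ctrl libraries, while Foxp3 stayed at 0.11 to 0.40 CPM in icKO and 0.38 to 1.54 CPM in Ctrl libraries.

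Further lists were higher with the preset correlation alone: cell cycle (median 0.59, adjusted p = 0.17 with an estimated correlation), interferon response (median 0.55, 0.26), NF-kB targets (median 0.13, 0.19), immediate early genes (median 0.37, 0.13) and cholesterol synthesis (median 0.32, 0.57). Tnfaip3, an NF-kB target that dampens NF-kB signalling, rose in the fit of 25 by 1.15 ± 0.24, and Sqle and Cyp51 of cholesterol synthesis rose by 1.07 and 0.99. Oxidative phosphorylation genes were lower (median -0.14, camera adjusted p = 0.0007, adjusted p = 0.52 with an estimated correlation), called in 7 of the 8 fits of 25 less 1 library (0.079 without Ctrl replicate 2). The monocyte and macrophage list was higher beside these lists (median 1.04, or 1.01 with members at 0 set to their bound, camera adjusted p = 4.5e-05, adjusted p = 0.26 with an estimated correlation), with 0 of 17 members called in the fit of 25, and the list was called in 6 of these 8 fits (0.079 without Ctrl replicate 2); Lyz2, an abundant gene of these cells, stayed under 9 CPM of library total, without TMM scaling, in each of the 8 CNS Tconv libraries.

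In 5 of the 8 CNS Tconv libraries the deposited file name carried a code that elsewhere marked the other genotype; groups followed the sample labels, and without these 5 libraries 3 genes were called in the fit of the remaining 21, and 158 when the library of 6005 genes was left out too. These fits set icKO replicate 1 alone against 2 Ctrl libraries, with the spread taken from the other groups. Leaving out CNS Tconv Ctrl replicate 1, 2 or 3 or icKO replicate 1, 3 or 4 left 4 to 6 genes in the fit of 26. Ccr7, Ly6c1 and Ndrg3 passed in each of the 8 fits without 1 of these libraries; Hif1a, Mapkapk3, Rab8b, Tpm4, Lcp1, H2-Ob, Il6ra and Rpl35 each missed the threshold in at least 6 of them (adjusted p = 0.057 to 0.25). With 25 libraries, 109 to 221 genes were called without Ctrl replicate 1 or 3 or icKO replicate 1, 3 or 4, and 796 without Ctrl replicate 4.

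**Figure D3:**
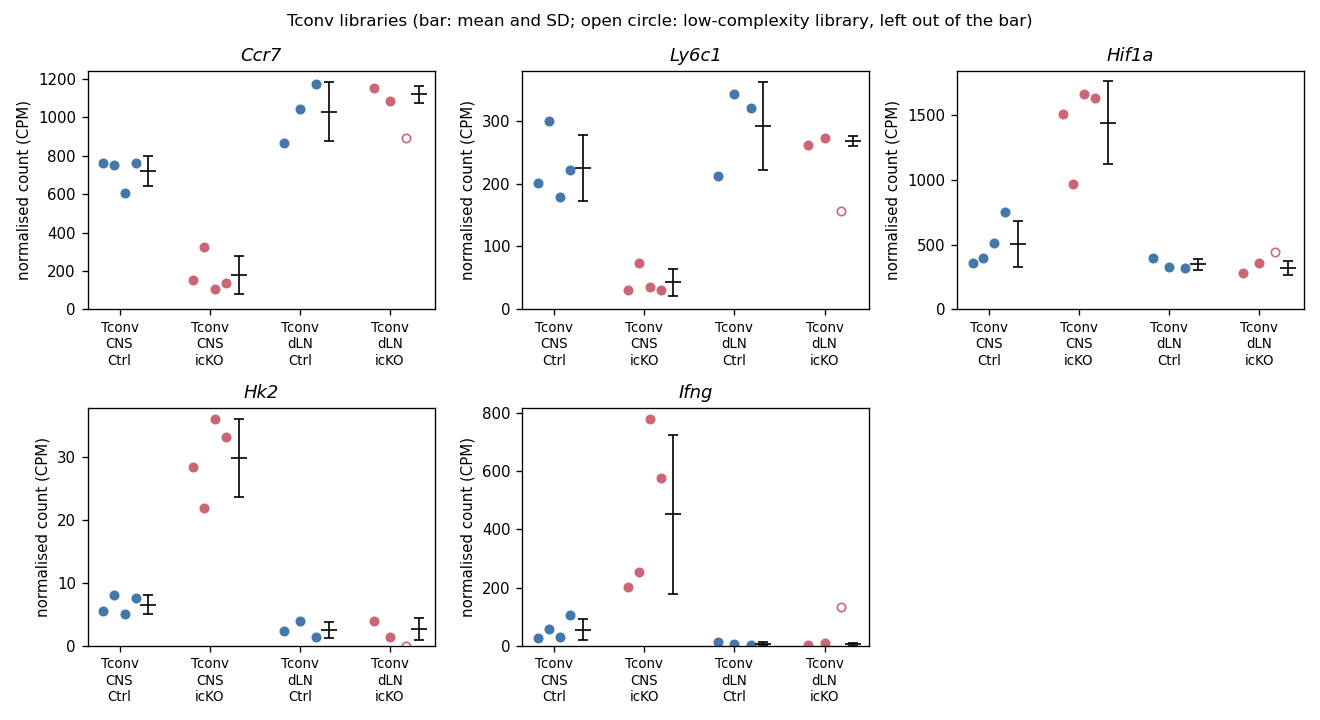
Normalised count (CPM, y axis) of 5 genes in each Tconv library by group (x axis), blue for Ctrl and red for icKO; bars give mean and SD without the open circle, the library of 6005 genes. Hk2 passed in the fit of 25, and Ifng, which did not pass, was picked for the plot after its values were seen. Ccr7 and Ly6c1 are lower and Hif1a higher in each CNS icKO library than in any CNS Ctrl library.

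**Figure D4:**
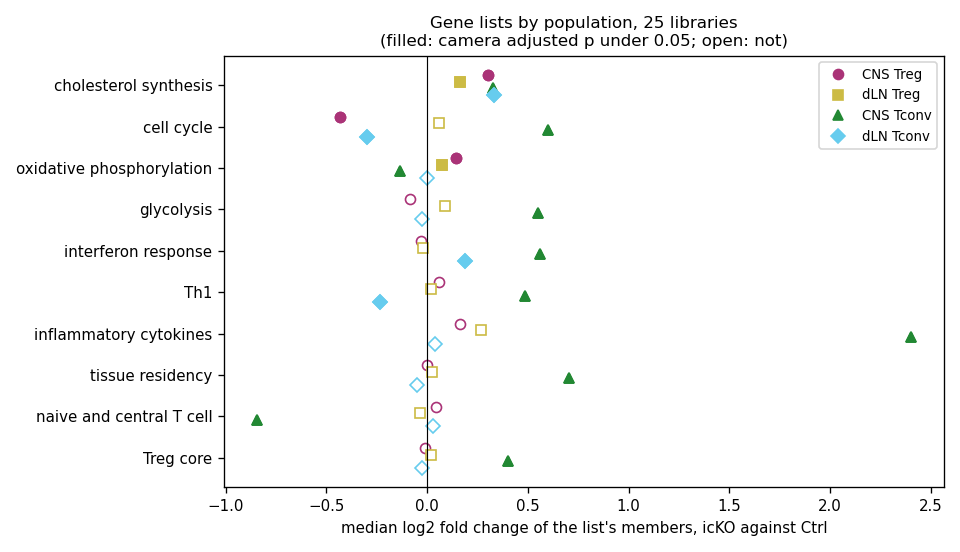
Median log2 fold change, icKO against Ctrl (x axis), of the members of 10 gene lists (y axis) in each population, fit of 25 libraries. Filled symbols passed camera with the preset correlation of 0.01. Inflammatory cytokines in CNS Tconv have 2.26 with members at 0 in a group set to their bound. The naive and central T cell list in CNS Tconv has a median of -0.85, and cholesterol synthesis is above 0 in all 4 populations.

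In dLN Tconv cells, the same comparison in the lymph nodes, edgeR called 0 genes in both fits, and no list passed camera in both. With 25 libraries (n = 3 Ctrl and 2 icKO) cholesterol synthesis was higher in icKO (median log2 fold change 0.33 over 20 genes, camera adjusted p = 1.1e-09), also with an estimated correlation (adjusted p = 0.041). 2 of its members passed adjusted over the list alone and 0 over all genes. Sqle, squalene epoxidase, had in that fit a value of 0.98 ± 0.27 (adjusted p = 1 over all genes). Also in the fit of 25, cell cycle genes were lower (median -0.30, camera adjusted p = 3.7e-06, adjusted p = 0.99 with an estimated correlation), Th1 genes were lower (median -0.23, camera adjusted p = 0.0086, adjusted p = 0.99 with an estimated correlation) and interferon response genes higher (median 0.19, camera adjusted p = 0.023, adjusted p = 0.99 with an estimated correlation). In the 5 fits of 25 less 1 library, cholesterol synthesis was called in all, cell cycle in 3 (adjusted p = 0.22 without icKO replicate 1) and Th1 in 2 (0.95 without icKO replicate 1). Interferon response was called in 4, with an adjusted p of 0.86 without Ctrl replicate 2, and it was higher in 4 and lower in 1.

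With all 26 libraries the median log2 fold change of all genes was -0.36, so list medians with 26 carry that shift. Cholesterol synthesis had a median of -0.04 there and did not pass (adjusted p = 0.64). At the preset correlation 9 other lists passed, all placed higher by camera: oxidative phosphorylation (median 0.14, camera adjusted p = 8.6e-06), NF-kB targets (median 0.34, 0.0009), Treg core (median 0.62, 0.0083), effector Treg (median 0.46, 0.019), Th17 (median 0.12, 0.019), IL-2 and STAT5 (median 0.27, 0.034) and immediate early genes (median -0.09, 0.045). The remaining pair were markers of other cells, neutrophils (median 6.75 with members at 0 in a group set to their bound, 0.00092) and monocytes and macrophages (median 1.83, 0.0015). None of the 9 passed with an estimated correlation (adjusted p = 0.16 or more) or in the fit of 25. Tnfrsf1b and Foxp3 changed the sign of their fold change between the fits, and 0 genes were called by limma and 48 by DESeq2. At an unadjusted p under 0.05 edgeR had 1092 genes with 26 libraries and 197 with 25, and it called 1 gene of the fit of 26 without icKO replicate 1. The 197 fall short of the share of 0.05 that no effect would give, so the shared spread of the fit of 25 may be too wide here.

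Control Treg cells of the CNS were compared with those of the dLN to describe how residence in inflamed tissue goes with the Treg transcriptome. At the preset correlation of camera, lists of Th1 and interferon response genes were higher and that of cell cycle genes lower in CNS Treg libraries; with an estimated correlation Th1 alone of these held, and not in the fit of 25. Cxcr6, a chemokine receptor of tissue T cells, was higher by 2.12 ± 0.31 on the log2 scale (adjusted p = 0.00048), and Ccl5, a chemokine of effector T cells, by 3.45 ± 0.61 (adjusted p = 0.0023). Mki67, a marker of proliferation, was lower (log2 fold change -2.48 ± 0.55, adjusted p = 0.01), and so was Itgae, the integrin chain CD103 (-2.19 ± 0.51, 0.015). Tnfrsf1b did not pass in either fit (-0.39 ± 0.60, adjusted p = 0.89, and 0.1 in the fit of 25).

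Of 17 Th1 genes 9 rose, 12 adjusted over the list alone (camera adjusted p = 2.3e-11, adjusted p = 0.0079 with an estimated correlation, and 0.11 in the fit of 25). Of 35 interferon response genes 17 rose, 26 adjusted over the list alone (camera adjusted p = 4.6e-18, adjusted p = 0.069 with an estimated correlation), with Irf7, a regulator of the interferon response, at 2.84 ± 0.37. Of 40 cell cycle genes 6 fell, 14 adjusted over the list alone (camera adjusted p = 6.0e-16, adjusted p = 0.062 with an estimated correlation), and 31 fell in the fit of 25. The histone genes Hist1h1b, Hist1h2ae and Hist1h3i, with Ttn and Cit, had the largest falls, of -3.49 to -2.60. Of 21 glycolysis genes 7 rose (camera adjusted p = 1.3e-05, adjusted p = 0.15 with an estimated correlation), and of 14 follicular helper genes 4 fell (camera adjusted p = 0.0013, adjusted p = 0.082 with an estimated correlation), among them Btla (-1.65) and Cxcr5 (-2.02). Of 23 immediate early genes, which also respond to tissue dissociation, 9 rose and 1 fell (camera adjusted p = 1.5e-06, adjusted p = 0.062 with an estimated correlation), with Fos at 5.39 ± 0.88. Inflammatory cytokine transcripts were higher (6 of 19 rose, camera adjusted p = 0.00082, adjusted p = 0.17 with an estimated correlation), including Csf2 and Ifng at 7.57 and 6.60; Il17a, at 0 in the dLN group, was at least 28.7-fold higher.

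Markers of other cells were higher in the CNS Treg libraries beside all of these lists. Of 11 microglia markers 10 rose (median 6.95 with members at 0 in a group set to their bound, camera adjusted p = 6.7e-23, also called with an estimated correlation, adjusted p = 0.0044, and 0.019 in the fit of 25). Of 17 monocyte and macrophage markers 8 rose (camera adjusted p = 3.4e-12, adjusted p = 0.062 with an estimated correlation), of 10 neutrophil markers 6 (camera adjusted p = 6.0e-07, adjusted p = 0.062 with an estimated correlation), of 13 dendritic cell markers 6 (camera adjusted p = 1.4e-06, adjusted p = 0.062 with an estimated correlation) and of 10 CD8 T and NK cell markers 4 (adjusted p = 0.03 with an estimated correlation, and 0.11 in the fit of 25). The 5 largest rises were Arg1, Nos2, Fcrls, Cd34 and Slc2a5, all at 0 in the 3 dLN libraries. Against a floor of 3 counts per library, Arg1, arginase, was at least 915-fold, Nos2, inducible nitric oxide synthase, at least 578-fold and Fcrls, a microglia marker, at least 512-fold higher.

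The fit of 26 called 751 genes, 535 higher and 216 lower, the fit of 25 called 2943 (1789 and 1154), DESeq2 1405 and limma 4095. Leaving out CNS Treg Ctrl replicate 1 or 2 or any of the 3 dLN Treg Ctrl libraries gave 201 to 352 genes in the fit of 26; in the fit of 25, 1665 were called without CNS replicate 2 and 1881 without dLN replicate 3. Mki67, Itgae, Ifng, Csf2, Il17a, Cxcr5, Nos2 and the histone genes missed the threshold of the fit of 26 without at least 1 library, most often CNS replicate 2 or dLN replicate 3 (adjusted p = 0.05 to 0.15).

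**Figure D5:**
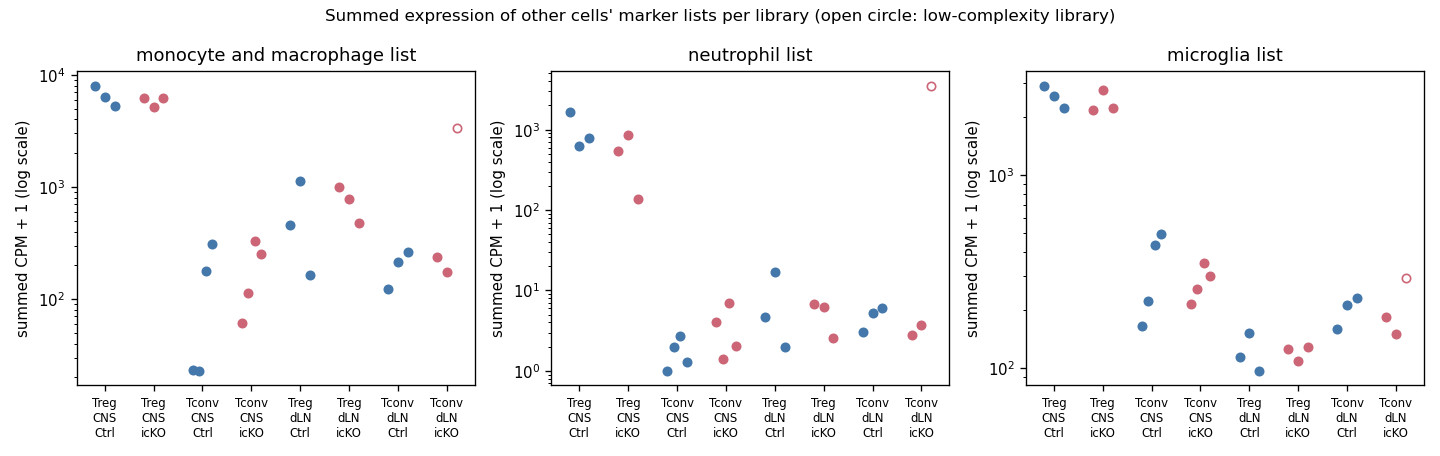
Summed CPM of library total plus 1 (y axis, log scale) of the monocyte and macrophage, neutrophil and microglia marker lists in each library by group (x axis), blue for Ctrl and red for icKO. The 6 CNS Treg libraries and the open circle, the dLN Tconv icKO library of 6005 genes, are highest for the monocyte and macrophage and the neutrophil lists.

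In control Tconv cells the same tissue comparison gave lists of Th1 and of migration and adhesion genes as higher in the CNS, also with an estimated correlation in both fits. Cxcr3 and Cxcr6, chemokine receptors of effector T cells, rose by 2.77 ± 0.41 and 2.30 ± 0.30 on the log2 scale (adjusted p = 0.0026 and 0.0021; n = 4 CNS, 3 dLN). Ccl5 rose from 22.3 ± 0.883 to 247 ± 85.7 CPM (3.47 ± 0.59, adjusted p = 0.0048), and Il2rb, an IL-2 receptor chain, rose by 1.62 ± 0.23. Id3 and Cxcr5, both high in follicular and central T cells, fell to 14.1 ± 3.88 and 15.9 ± 5.68 CPM (-2.44 ± 0.41 and -2.32 ± 0.39, adjusted p = 0.0048). Tnfrsf1b rose in the fit of 25 (0.75 ± 0.16, adjusted p = 0.0046) and did not pass in the fit of 26 (adjusted p = 0.82).

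Of 17 Th1 genes 5 rose, 10 adjusted over the list alone, and of 31 migration and adhesion genes 4 rose, 13 adjusted over the list alone; both lists were called with an estimated correlation (adjusted p = 0.00086 and 0.0018). So were effector Treg genes (4 of 24 rose), Treg core genes (6 of 24), IL-2 and STAT5 signalling (3 of 20) and Th17 genes (2 of 18), while follicular helper genes were lower (2 of 14 fell). In the fit of 25 the follicular helper and Th17 lists missed this threshold (adjusted p = 0.054 and 0.068). Naive and central T cell genes were lower too, with 2 of 18 called (camera adjusted p = 7.0e-05, adjusted p = 0.22 with an estimated correlation). The largest rises were Tppp3, Jun, Metrnl, Ccl5 and Socs2, a target of STAT5, at 3.30 to 4.97. Immediate early genes, which also respond to dissociation, were higher (5 of 23 rose, camera adjusted p = 3.6e-05, adjusted p = 0.083 with an estimated correlation), with Jun at 4.71 ± 0.96 and Junb at 1.78 ± 0.29. Cd209b, a lectin of lymph node macrophages, fell from 57.7 ± 24.1 CPM in dLN to 0.0378 ± 0.0756 CPM in CNS libraries, and the chemokine gene Ccl8 from 69.1 ± 33.6 to 0.28 ± 0.361 CPM. The microglia list was higher in the CNS (2 of 11 rose, camera adjusted p = 1.4e-05, adjusted p = 0.13 with an estimated correlation). The camera test put the monocyte and macrophage list lower (camera adjusted p = 0.00068, adjusted p = 0.41 with an estimated correlation), while its median was 0.24; it was called in 5 of the 7 fits of 25 less 1 library (adjusted p = 0.21 without CNS replicate 2).

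The fit of 26 called 143 genes, 113 higher and 30 lower, the fit of 25 called 1202 (806 and 396), DESeq2 439 and limma 1753. Without CNS Tconv Ctrl replicate 4 the fit of 26 called 342 genes, and without any 1 of the other 6 libraries 23 to 86; in the fit of 25, 2473 without that replicate and 407 to 711 without CNS replicate 1 or 2 or any dLN library. Without the CNS Tconv libraries whose file names disagreed, which leaves 2 CNS libraries, the counts were 173 (119 higher and 54 lower) and, from the fit of 25, 2374 (1160 and 1214). Jun, Junb, Socs2, Ccl5 and Tppp3 missed the threshold of the fit of 26 without 1 to 4 libraries, dLN replicate 3 among them (adjusted p = 0.05 to 0.13).

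Treg and Tconv cells of control mice were compared within each tissue. In the CNS, Treg libraries had higher transcripts of the Treg programme and of TNF receptors, and lower transcripts of naive T cells. Foxp3 was higher by 5.36 ± 0.81 on the log2 scale (adjusted p = 0.00059; n = 3 Treg, 4 Tconv). Itgae rose by 4.83 ± 0.52, Ikzf2, the Treg transcription factor Helios, by 2.97 ± 0.36 and Tnfrsf9 by 3.74 ± 0.58. Tnfrsf1b had a log2 fold change of 1.56 ± 0.56 (adjusted p = 0.11) and rose in the fit of 25 (adjusted p = 7.1e-07).

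Of 24 Treg core genes 16 rose, 19 adjusted over the list alone, and of 14 TNF receptor genes 5 rose, 7 adjusted over the list alone; with an estimated correlation the adjusted p were 1.3e-07 and 0.0031. Effector Treg genes (7 of 24 rose) and Th2 genes (1 of 10) were higher, and naive and central T cell genes lower (8 of 18 fell), all called with an estimated correlation. The largest falls were Dapl1 (-5.29 ± 1.02), Tmie, Igfbp4, Trnp1 and Hid1 at -4.46 to -2.85. Cd40lg, the ligand of CD40 on helper T cells, fell by 1.99 on the log2 scale and Cxcr6 by 1.84.

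Myeloid markers were higher in CNS Treg than in CNS Tconv libraries beside these lists: 16 of 17 monocyte and macrophage genes, 9 of 10 neutrophil genes and 7 of 11 microglia genes rose, called with an estimated correlation (adjusted p = 0.0043, 0.024 and 0.0043). Lyz2, lysozyme, rose by 8.06 ± 1.35 and Apoe, apolipoprotein E, by 6.37 ± 1.05. Chil3, Pla2g7, Il1b, Nos2 and Tnfaip2 had the largest rises and were at 0 in all 4 CNS Tconv Ctrl libraries. Chil3, a lectin of activated macrophages, was at least 3964-fold and Il1b, interleukin 1 beta, at least 665-fold higher. Inflammatory cytokines were higher as a list in the fit of 26 (4 of 19 rose, camera adjusted p = 0.034, adjusted p = 0.42 with an estimated correlation) and did not pass in the fit of 25 (camera adjusted p = 0.11, called in 1 of the 7 fits of 25 less 1 library), and the called members with the smallest p were Il1a, Il1b and Il6.

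The fit of 26 called 794 genes in this comparison, 571 higher and 223 lower, the fit of 25 called 2411 (1462 and 949), DESeq2 1285 and limma 2037. Without CNS Treg Ctrl replicate 2 these counts were 446 and 1581, and without the 5 CNS Tconv libraries whose file names disagreed with the labels 518 in the fit of 21 libraries. Tmie and Hid1 missed the threshold of the fit of 26 without CNS Treg replicate 1 or 2 (adjusted p = 0.069 to 0.12), and Hid1 also without Treg replicate 3 or Tconv replicate 1 or 2.

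In the dLN, too, Treg libraries had higher transcripts of Treg core genes than Tconv libraries. Tnfrsf1b averaged 806 ± 53.9 CPM in Treg and 124 ± 9.47 CPM in Tconv Ctrl libraries and rose by 2.70 ± 0.63 (adjusted p = 0.026, n = 3 each). Foxp3 rose by 5.57 ± 0.92 (adjusted p = 0.0019), Lrrc32, the TGF-beta docking receptor GARP, by 8.51 ± 1.72 and Itgae by 6.03 ± 0.61. Of 24 Treg core genes 19 rose, 22 adjusted over the list alone. Cell cycle genes were higher (median 1.59, 4 of 40 rose, 25 adjusted over the list alone), and naive and central T cell genes lower (10 of 18 fell, 14 adjusted over the list alone).

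With an estimated correlation the dLN calls held for Treg core (adjusted p = 3.3e-11), cell cycle (0.0094, but 0.069 in the fit of 25) and naive and central T cell genes (0.0013), and for effector Treg, TNF receptor, Th2, inhibitory receptor, and IL-2 and STAT5 genes. CD8 T and NK cell markers were lower in Treg libraries (2 of 10 fell, adjusted p = 0.0016 with an estimated correlation), with Prf1, perforin, at -4.38 ± 0.59. Ahr, the aryl hydrocarbon receptor, rose by 3.10 ± 0.30 and Ikzf2 by 4.49 ± 0.43. Satb1, a chromatin organiser of naive T cells, fell by 1.66 and Lef1 by 2.06 on the log2 scale. The other largest rises were Rln3 and Dgat2 (5.60 and 5.05). The largest falls were Klk1, Dapl1, Olfml3 and Pdlim4, at -7.99 to -5.43 from few counts in the Treg libraries, and Lrrc75b, at 0 in the Treg libraries and at least 51.7-fold lower. The fit of 26 called 235 genes, 121 higher and 114 lower, the fit of 25 called 1556 (816 and 740), DESeq2 661 and limma 3657. Leaving out any 1 of the 6 libraries gave 85 to 144 genes in the fit of 26, and Tnfrsf1b missed the threshold in each of these 6 fits (adjusted p = 0.057 to 0.14), while it passed in the fit of 25 (adjusted p = 5.1e-09). Lrrc32 missed it without Tconv replicate 1 or 3 (0.059 and 0.074), and Rln3, Dgat2, Klk1 and Pdlim4 without at least 5 of the 6 libraries (0.064 to 0.22). With 25 libraries as the base, 891 to 1025 genes were called without Treg replicate 1 or 3 or Tconv replicate 2 or 3.

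Interaction contrasts tested whether differences varied between populations. For the genotype difference of Treg cells between CNS and dLN, no single gene passed: edgeR called 0 genes in both fits, with 133 and 449 at an unadjusted p under 0.05, DESeq2 2 and limma 0. Both numbers fall short of the share of 0.05 that no effect would give, so the shared spread may be too wide here. In the fit of 25, cell cycle genes were lower in icKO relative to the dLN (median -0.47, camera adjusted p = 1.1e-05, adjusted p = 0.95 with an estimated correlation), and so were glycolysis genes (median -0.23, camera adjusted p = 0.04, adjusted p = 0.95 with an estimated correlation). The lists of endothelium and fibroblasts (camera adjusted p = 0.025, adjusted p = 0.95 with an estimated correlation) and astrocytes (camera adjusted p = 0.038, adjusted p = 0.95 with an estimated correlation) were lower beside them in that fit, and the same 4 lists passed at the preset correlation in the fit of 26. In the 12 fits of 25 less 1 library, the cell cycle call was lost without CNS Treg Ctrl replicate 3 (adjusted p = 0.44), and glycolysis was called in 5 (0.92 without CNS Treg Ctrl replicate 2), endothelium and fibroblasts in 7 and astrocytes in 5. In the fit of 25 Prmt5 had the smallest p (-0.95 ± 0.19, adjusted p = 0.76), and Tnfrsf1b had -0.23 ± 0.23 (adjusted p = 1). Without CNS or dLN Treg icKO replicate 1 the fit of 25 called 1 gene.

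The genotype difference in the CNS differed between Treg and Tconv libraries in the fit of 25, where 24 genes passed, 15 with a higher and 9 with a lower difference in Treg cells. Tnfrsf1b was among them: its genotype difference was lower in Treg than in Tconv libraries, at -1.31 ± 0.22 on the log2 scale in that fit (adjusted p = 0.024). In the same fit, Ly6c1 (2.73 ± 0.43), Il6ra (1.84 ± 0.38) and Cd8b1 (2.44 ± 0.43) had higher differences in Treg libraries. The cell cycle regulators Wee1 (-1.97 ± 0.40), Plk4 (-1.69 ± 0.32), G2e3 and Cdca2 had lower ones (-2.40 and -1.60). By genotype, that fit called Tnfrsf1b higher and Ly6c1 and Il6ra lower in icKO CNS Tconv libraries. It called 0 genes in CNS Treg libraries, so these contrasts alone do not show a change in Treg cells. Naive and central T cell genes had a higher difference in Treg libraries (2 of 18 called, 13 adjusted over the list alone), called with an estimated correlation in the fit of 25 (adjusted p = 0.029) and not in the fit of 26 (0.057). With 25 libraries, glycolysis (median -0.71, camera adjusted p = 2.8e-11, adjusted p = 0.46 with an estimated correlation) and cell cycle genes (median -1.05, camera adjusted p = 9.4e-14, adjusted p = 0.48 with an estimated correlation) had lower ones. Of the lists of other cells in that fit, CD8 T and NK markers had a higher difference in Treg libraries (median 0.81, camera adjusted p = 0.0085, adjusted p = 0.48 with an estimated correlation), called in 13 of the 14 fits of 25 less 1 library. Monocyte and macrophage markers had a lower one there (median -1.12, camera adjusted p = 0.021, adjusted p = 0.64 with an estimated correlation), called in 8 of the 14.

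With all 26 libraries edgeR called 0 genes in this contrast, with 667 at an unadjusted p under 0.05, DESeq2 51 and limma 3; Ly6c1 had an adjusted p of 0.074. Without CNS Tconv Ctrl replicate 1 it called 1 gene and without CNS Tconv icKO replicate 2 it called 3. Without the CNS Tconv libraries whose file names disagreed the counts were 1 and, from the fit of 25, 71 (23 higher and 48 lower). Of the fits of 25 less 1 library, 0 genes were called without CNS Treg Ctrl replicate 2 or CNS Tconv icKO replicate 1, 1 gene without CNS Tconv Ctrl replicate 3, 4 without CNS Treg icKO replicate 2, 14 or 15 without CNS Tconv icKO replicate 3 or 4, and 41 to 263 without CNS Treg Ctrl replicate 3, CNS Treg icKO replicate 1 or 3 or CNS Tconv Ctrl replicate 2 or 4.

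The tissue difference in control mice differed between Treg and Tconv cells for 12 genes in the fit of 26, 10 with a higher and 2 with a lower difference in Treg cells. Among them were genes of myeloid cells and microglia: Gpr141, Cd300ld, Siglece and Olfml3, at 8.65 to 10.11, sizes that rest on few counts in at least 1 group, and App (4.42 ± 0.74, adjusted p = 0.015). Ahr (-2.21 ± 0.39) and Ahnak (-2.19 ± 0.38) had a lower CNS difference in Treg than in Tconv cells (adjusted p = 0.015). Of 24 Treg core genes 2 had a lower difference adjusted over the list alone and 0 over all genes (median -0.92, adjusted p = 0.0034 with an estimated correlation). The monocyte and macrophage list was higher (adjusted p = 0.0077 with an estimated correlation, 16 of 17 adjusted over the list alone). Tnfrsf1b passed in the fit of 25 (-1.13 ± 0.23, adjusted p = 0.0068), where 495 genes were called, 344 higher and 151 lower; DESeq2 called 276 and limma 910. Without CNS Treg replicate 1 or any 1 of the 3 dLN Treg libraries the fit of 26 called 3 to 8 genes, and without CNS Tconv replicate 4 it called 50. Without the CNS Tconv libraries whose file names disagreed the counts were 110 (100 higher and 10 lower) and, from the fit of 25, 1129 (779 and 350). Ahr, Ahnak, App, Gpr141 and Olfml3 all missed the threshold without dLN Treg replicate 1 or 3 (adjusted p = 0.063 to 0.15). With 25 libraries the count was 252 to 298 without Treg replicate 1 or 2 from the CNS or 1 or 3 from the dLN, or dLN Tconv replicate 2 or 3, and 752 and 920 without CNS Treg replicate 3 and CNS Tconv replicate 4.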

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

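The splits of the libraries for the 3 interaction contrasts were planned before their results were seen. They exchanged labels within each pair of groups and never between cell types. The count of splits that mixed the labels within both pairs was chosen after the results were seen. So were the other splits and the tests of the 3 patterns below. In groups of 4, the gap of the most extreme library to its neighbour was compared with the range of the group for 32 measures, and 4 exceeded the critical value of Dixon's test. Chance gives about 1 in 20 such groups. In CNS Tconv Ctrl libraries the ratio was 0.838 for Lcp1, with replicate 2 lowest, and 0.929 for Ccr7, with replicate 3 lowest. In CNS Tconv icKO libraries it was 0.832 for the log2 total count, with replicate 1 highest, and 0.852 for Foxp3, with replicate 1 lowest.

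The genotype difference in the CNS varied between Treg and Tconv cells in the fit of 25, with 24 genes called by the interaction contrast. Tnfrsf1b had a value of -1.31, with a rise called in CNS Tconv and no change called in CNS Treg libraries. Higher differences in Treg cells included those of Tmie (4.34), Ly6c1 (2.73), Sqor (2.45), Cd8b1 (2.44), Il6ra (1.84), Atn1 (1.68), Mfge8 (1.55), Nipbl (1.41) and Rps27rt (1.30). Lower differences were found for G2e3 (-2.40), Wee1 (-1.97), Smox (-1.85), Plk4 (-1.69), Cdca2 (-1.60), Fbxw8 (-1.07), Fam53c (-0.87) and Plekha2 (-0.84). Of 40 splits drawn, 3 called at least as many genes, the real one included. The highest other called 281 and kept the CNS Tconv genotype groups whole, so it carries their difference. Of the splits that mixed the genotype labels within both cell types the highest called 48, so chance is not excluded. With 26 libraries the real split called 0 genes and the highest other 18; with a count of 0, its 40 of 40 splits as large say nothing about chance.

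The tissue difference of control mice varied between Treg and Tconv cells, with 12 genes called in the fit of 26 and 495 in the fit of 25. Among the named genes, Gpr141 (10.1), Cd300ld (9.40), Siglece (8.80), Olfml3 (8.65) and App (4.42) had higher and Ahr (-2.21) and Ahnak (-2.19) lower differences in Treg cells. Of 40 splits drawn, 2 called at least as many genes, the real one included. The highest other split, with 477 genes from 26 and 2702 from 25 libraries, kept the Treg tissue groups whole and so carries their difference. Splits that mixed the tissue labels within both cell types called at most 0 and 1 genes. They also take the tissue differences away, so these counts do not decide on chance.

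Other regroupings of the same libraries were counted for the remaining contrasts. For CNS Tconv cells by genotype, 1 of 35 splits, the real one, called as many genes (12, highest other 0). With 25 libraries the counts were 419 and 179. For CNS Treg against Tconv cells it was also 1 of 35 (794 and 379, and with 25 libraries 2411 and 2199). The highest other split of the fit of 25 set CNS Tconv Ctrl replicates 1 to 3 against the rest. In both comparisons 1 of 35 is the smallest share that the splits allow. These splits were chosen after the results were seen, so the share argues against chance and does not exclude it. For Tconv cells of CNS against dLN, 2 of 35 splits called as many (143 and 288; with 25 libraries 1202 and 2494), so chance is not excluded. The larger split put CNS Tconv Ctrl replicate 4 with the 3 dLN libraries. The highest rank correlation of that replicate was with dLN Tconv Ctrl replicate 3 (0.977), against 0.972 within its own group. This points to a structure of the samples, and its cause was not tested. The 3-against-3 comparisons have 10 splits, too few for a share under 0.05. The real and highest other counts were 751 and 0 (25 libraries 2943 and 0) for Treg cells of CNS against dLN and 235 and 0 (1556 and 0) for Treg against Tconv cells of the dLN, with 1 of 10 splits as large. By genotype they were 0 and 0 (25 libraries 0 and 9) for CNS Treg, 0 and 0 in both fits for dLN Treg, and 0 and 1 for dLN Tconv cells with 26 libraries, with 10 of 10 as large. For the genotype difference of Treg cells between tissues, the counts were 0 and 0 (0 and 1 with 25 libraries), so its 40 of 40 splits as large say nothing about chance either.

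The library labelled dLN Tconv icKO replicate 3 stood apart from the other 25. Of the genes at 50 CPM or more in all other dLN Tconv libraries, 25.9% were under 1 CPM in it. In contrast, 7 genes of the T cell receptor complex and its signalling had a median ratio of 1.44 to those libraries. Cd3e was at 1141 and Gnai3 at 0 CPM of library total, values that few RNA molecules in the library could give. Dilution by RNA of other cells would lower all T cell genes alike. Yet 37.7% of the genes at 50 CPM or more lay under 0.25 times the ratio of these 7 genes, which argues against dilution for the missing genes. The genotype is argued against by the other icKO libraries, whose rank correlation with a Ctrl library was at least 0.986. RNA of other cells as the source of the raised genes stays open: the neutrophil list had a median log2 ratio of 4.10, with S100a8 at 1592 against 0.545 CPM, and the monocyte and macrophage list 3.21, with 11 of 17 members raised more than 2-fold. The test also required a majority of the B cell list to be raised more than 2-fold, and this was not met: 3 of 10 members were, and the list had a median log2 ratio of -0.0583. Few molecules can also make single genes high.

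CNS Tconv libraries differed between the genotype labels, and 5 of the 8 carried file-name codes of the other genotype. Grouped by code, edgeR called 0 genes in the fit of 25, with 1126 at an unadjusted p under 0.05, against 419 called by label, so the difference follows the labels. Whether the labels or the codes give the genotype cannot be told apart from these counts, since a difference of another origin may follow the labels too. A different mix of naive and effector T cells may account for the difference: genes high in the CNS, chosen on 1 pair of Ctrl libraries, were higher in icKO than in the other pair by a median of 0.83 (115 genes) and 1.18 (75 genes). An effect of the genotype on the cells or on which cells enter the CNS stays open, as does any difference between mice that goes with the labels.

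CNS Treg libraries held many transcripts of myeloid cells. RNA of myeloid cells in these samples is a candidate source, since 16 of 17 monocyte and macrophage markers were called higher than in CNS Tconv libraries, and in the Ctrl libraries Lyz2 averaged 1141 and Apoe 907 CPM of library total (n = 3), against 4.37 for Lyz2 in CNS Tconv Ctrl. The labels describe the cells as highly purified, which such RNA would have to pass. The neutrophil and microglia lists were also called higher than in CNS Tconv libraries. Both passed in all 7 fits without dLN Tconv icKO replicate 3 and a further library (camera adjusted p up to 6.4e-08). S100a8 averaged 230 ± 149 CPM of library total in CNS Treg Ctrl, against 0.18 ± 0.31 in CNS Tconv Ctrl. Expression by CNS Treg cells alone would need markers of all these cell types at once, which argues against it as the only source. A part from CNS Treg cells stays open. In dLN Treg libraries 0 monocyte and macrophage markers were called higher than in dLN Tconv libraries, but tissue Treg cells have no counterpart among the other samples.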

How the results depend on the processing

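The fits without the low-complexity dLN Tconv icKO library were chosen after seeing the data; the other alternatives were planned. Across the 26-library results, the number of called genes stayed within 1.5 times in 111 cases and moved in 73; of the values of named genes 3505 kept direction and side of the threshold, 612 missed it, 37 newly passed and 10 reversed. For gene lists 640 results stayed the same, a count that includes numbers of list calls within 1.5 times beside adjusted p that kept direction and side. Of the adjusted p 201 lost the call and 7 reversed, and 2 numbers of list calls moved. Without the low-complexity library the counts were 419 for CNS Tconv cells by genotype (12 with it), 2943 and 1202 for CNS against dLN in Treg and Tconv cells (751 and 143), 2411 and 1556 for Treg against Tconv in CNS and dLN (794 and 235), and 24 and 495 for the interactions of genotype and of tissue with cell type (0 and 12); the common dispersion fell from 0.364 to 0.142 with it. In the same order, DESeq2 called 120, 1405, 439, 1285, 661, 51 and 276 genes, and limma 445, 4095, 1753, 2037, 3657, 3 and 910. DESeq2 also called 2 genes in CNS Treg, 5 in dLN Treg and 48 in dLN Tconv cells by genotype and 2 for the genotype difference of Treg cells between tissues, and limma 2 in dLN Treg cells; the cause was not tested. Models of the compared groups alone called 102 genes for CNS Tconv cells by genotype, 2809 and 285 for the tissues, 2935 for dLN Treg against Tconv and 274 for the interaction of tissue and cell type. The replicate block, in which numbers need not mark the same mouse, gave 2477 and 861 for the tissues, 3075 for dLN Treg against Tconv and 533 for that interaction. Correlations of the libraries' deviations from their group means did not settle the pairing. In dLN Treg against Tconv they were 0.0895 to 0.283 for same numbers and at most 0.0923 for different ones. In CNS Treg against Tconv they were -0.0595 to 0.145 and at most 0.409. For CNS against dLN they were -0.00973 to 0.157 and at most 0.065 in control Treg cells, and -0.21 to 0.0508 and at most 0.262 in control Tconv cells. The main contrasts treat these libraries as unpaired. For CNS Tconv cells by genotype, no filter gave 4 genes and the strict filter 22. Without the 5 CNS Tconv libraries with disagreeing file names the counts were 3 for CNS Tconv cells by genotype, 518 for CNS Treg against Tconv, and 1 and 110 for the interactions of genotype and of tissue with cell type; from the fit of 25 these were 158, 2584, 71 and 1129, and 2374 for Tconv cells by tissue. Fewer samples are part of that alternative, which leaves 1 CNS Tconv icKO library against 2 Ctrl libraries. camera made 141 calls at its preset correlation and 41 with an estimated correlation, and fry made 82.

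Leaving out each library in turn from the fit of 26 gave 0 genes in each case for CNS and dLN Treg cells by genotype, 4 to 13 for CNS Tconv and 0 to 1 for dLN Tconv cells. It gave 201 to 754 and 23 to 342 for the tissues in Treg and Tconv cells, 446 to 820 and 85 to 144 for Treg against Tconv in CNS and dLN, and 0, 0 to 3 and 3 to 50 for the interactions. From the fit of 25 the genotype ranges were 0 to 13, 0 to 1, 109 to 796 and 0. Where 1 library of an arm of 2 remained, it was assumed to vary like the other groups. Reversed values came from dLN Tconv cells by genotype: without the low-complexity library, as a replicate or as an alternative, Tnfrsf1b had a log2 fold change of 0.0693 and Foxp3 of -0.62, and with limma 0.0702 and -0.60; over the fits without 1 library Tnfrsf1b ran from -0.94 to 0.0693 and Foxp3 from -0.62 to 2.73. There, lists changed direction without that library with adjusted p of 0.488 for Treg core and for neutrophil markers, 0.285 for effector Treg, 0.997 for Th17, 0.607 for IL-2 and STAT5 signalling and 0.698 for monocyte and macrophage markers, and with fry 0.986 for immediate early genes. Foxp3 also reversed for Tconv cells by tissue without CNS Tconv Ctrl replicate 4 (0.0337, range over single libraries from -0.61) and in the interaction of tissue and cell type without CNS Treg Ctrl replicate 1 or 2 (0.02 each) or CNS Tconv Ctrl replicate 3 (range -0.81 to 0.19); the cause was not tested. With 3 counts as the floor, the depth limits folds against groups at 0, and the spread between libraries limits the rest.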

Other observations

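The tests of Ide and the use of the fit of 25 libraries were chosen after the results were seen. Genes of cholesterol synthesis lay higher in icKO libraries of all 4 populations in the fit of 25, a pattern that rests on leaving out 1 library, with medians of 0.30 in CNS Treg, 0.16 in dLN Treg, 0.33 in CNS Tconv and 0.33 in dLN Tconv cells. In the planned fit of 26 the medians were 0.29, 0.18, 0.32 and -0.04, and the preset call was made in the CNS populations alone (adjusted p = 0.0038 and 0.043, against 0.11 and 0.64). With an estimated correlation the call held in dLN Tconv cells of the fit of 25 alone (adjusted p = 0.041, against 0.25, 0.83 and 0.24). In the fits of 25 less 1 library the preset call was made in 4 of 6 for CNS Treg, 3 of 6 for dLN Treg, 8 of 8 for CNS Tconv and 5 of 5 for dLN Tconv cells.

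Ide, the insulin-degrading enzyme on chromosome 19, was lower in icKO libraries of 3 populations, and an effect of the genotype shared by all cells was considered as a hypothesis. The group means, as scaled for the fit of 25, were 235 CPM in Ctrl and 139 CPM in icKO for CNS Treg, 309 and 179 CPM for dLN Treg, and 201 and 111 CPM for dLN Tconv cells (n = 3 each, 2 for dLN Tconv icKO). The log2 fold changes in that fit were -0.76 ± 0.22, -0.79 ± 0.22 and -0.86 ± 0.26 (edgeR adjusted p = 0.6, 1 and 1). In CNS Tconv cells its log2 fold change was 0.19 ± 0.19 in the fit of 25 (192 CPM in Ctrl and 219.6 CPM in icKO, n = 4 each). By the labels this lay above each of the other values by more than 2 SE of the difference. Ide was picked after its low values in the other populations were seen, which widens this gap. The gap therefore does not decide on an effect of similar size in all cells. In this population 5 of 8 file names carry the code of the other genotype. Grouped by code, the value from the same 25 libraries was -0.24 ± 0.20 (n = 3 and 5), within 2 SE of another population, so the hypothesis stays open.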
